A study of Mus musculus with 8 samples.

How the data were processed

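RNA was measured in single cells of mouse hippocampus in 8 droplet libraries made with a 10x Genomics 3′ kit. Per the labels' protocols, mice were perfused, hippocampi were dissociated with enzymes and a mechanical dissociator, myelin debris was removed by density centrifugation, red blood cells were lysed, and hippocampi of 3 mice were pooled per library, with 6 mice per group. The 4 groups were Control-Veh, RSD-Veh, Control-PLX and RSD-PLX. RSD is the stress named in the series title, PLX is the diet given to deplete microglia, and Veh is the control diet. The abbreviations are not spelled out in the labels, and doses and durations are not given there. Each group had 1 library in each of 2 cohorts, and the series design text states that the cohorts were barcoded and sequenced separately.

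The deposited matrices hold UMI counts per gene and cell barcode without normalization, as whole numbers for 31053 genes. Per the submitters' processing notes, Cell Ranger and Seurat were used with genome build mm10, and per the file headers the matrix software version was 3.1.0. The matrices were already restricted to called cells, and the settings of that step are not stated. The labels state about 3000 to 5000 cells recovered per sample, the matrices hold 1326 to 3812 barcodes per library, and no cell filter of the authors is stated. Gene symbols were taken from the deposited feature lists, which pair them with Ensembl identifiers, and 30934 of the 31053 identifiers were matched to the GENCODE vM21 annotation of GRCm38 for coordinates. Genes with near-identical copies (the alpha and beta globins, Lyz2 and Lyz1, C4b and C4a, Hspa1a and Hspa1b, and ribosomal protein genes with their pseudogenes) share reads, so their values are uncertain.

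Barcodes with at least 200 genes and at most 20% mitochondrial counts were kept, which left 17319 of 19809. Doublets were called with Scrublet in scanpy 1.11.5 in each library at an expected rate of 3%, and the 221 called cells (1.28%) were dropped after clustering. The called share ran from 0.217% in RSD-Veh 2 to 3.53% in Control-Veh 1. Counts were scaled to 10000 per cell and logged, and 2000 variable genes, 30 principal components, 15 exact neighbours and Leiden clustering at resolution 1 gave 30 clusters, with all libraries clustered together and without batch integration. Clusters were named from 149 marker genes: a name needed at least 3 raised markers and a score 0.5 above the next class. Clusters in which over 25% of the cells were called doublets (4 clusters) stayed unnamed, and clusters with no name or with a second class score over 2.5 were divided once more; both thresholds were set after the data were seen. These steps left 17098 cells, of which 16944 had a name. The unnamed doublet clusters held 0.746% of the cells of Control-Veh, 0.962% of RSD-Veh, 0.392% of Control-PLX and 0.445% of RSD-PLX, and the other unnamed cells held 0.115%, 0.141%, 0.275% and 0.178%.

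Raw counts were summed per library and class wherever a class had at least 10 cells in a library. The sums were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM normalization, filterByExpr with a minimum count of 10) in R 4.3.3, 1 fit per class with the 4 groups and the cohort as terms. Adjusted p is the Benjamini-Hochberg value within a class and comparison, called at 0.05, and 12 classes could be tested. Totals over classes are numbers of calls, so a gene counts once for each class in which it was called. Fold changes are log2 values from that fit. The SE given with a fold change, also for cell numbers, is its absolute value divided by the square root of the F value. It is thus derived from the test and is not a standard error estimated by the fit. Where every library of a group was at 0, the fold is a lower bound against 3 counts over that group. The 5 comparisons were stress in vehicle mice, stress in PLX mice, PLX in control mice, PLX in stressed mice, and the difference between the stress effects (interaction). On log CPM values with a prior count of 2, 16 gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 wherever at least 5 members were tested, which gave 500 tests with Benjamini-Hochberg adjustment per comparison, and again with an estimated correlation. Camera compares a list with the other genes tested in the class. Where a list is said to rise, fall or lie above or below 0, its adjusted p thus tests it against those genes and not against 0. The share of microglia-like cells was compared by an exact two-sided permutation test, and the number of cells per class by edgeR with all cells, or for other classes all cells outside the microglia-like class, as offset.

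The cohort was a block because the series design text ties it to separate barcoding and sequencing. As a check, the deviations of libraries of the same cohort from their group means correlated at 0.19 to 0.31 in astrocyte-like cells, 0.12 to 0.37 in microglia-like cells, 0.10 to 0.25 in oligodendrocyte-like cells and 0.24 to 0.33 in endothelial-like cells. The gene test was tested on simulated data drawn from the real means and library sizes with 200 changed genes. For stress in vehicle mice it recovered 97% of 4-fold and 46% of 2-fold changes among 7365 genes in microglia-like cells, 79.5% and 22% among 5450 genes in endothelial-like cells, and 70.5% and 7% among 1822 genes in mural-like cells. For PLX in control mice it recovered 71.5% and 4.5% in microglia-like cells. False calls made up 0% to 18.2% of the calls over all simulated settings, so the rate of 5% was not always held. For stress in vehicle mice they made up 1.02% and 1.08% in microglia-like, 6.47% and 8.33% in endothelial-like and 4.73% and 17.7% in mural-like cells. For PLX in control mice they made up 1.38% and 18.2% in microglia-like cells, the latter being 2 false calls beside 9 recovered genes.

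Markers, gene lists, settings, tests and the rule for named genes were fixed before the data were examined, apart from the thresholds stated above and those tests of technical explanations that are named as chosen later. The rule took, per comparison, Csf1r, Cx3cr1 and P2ry12 in microglia-like cells. It then took the 8 called genes with the smallest p in each of the 3 classes with the most calls that moved the same way in both cohorts and were not markers of another class. It added up to 4 called members of each list that passed its test or had at least 2 called members, and for the interaction the 8 genes with the smallest p. Alternatives were DESeq2 1.42.0, no filter on low counts, no replicate block, doublets kept, at least 300 genes and at most 10% mitochondrial counts, at least 30 cells per class and library, markers of other classes left out, another offset for cell numbers, and each library left out in turn. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for the other steps. Classes with fewer than 10 cells in a library of a compared group were left out of that gene comparison. Values of 1 gene among those called are not reported here.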

Results

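The data are RNA counts of single cells from the dissociated hippocampus of mice in 4 groups with 2 libraries each. These were unstressed and stressed mice on the control diet (Control-Veh and RSD-Veh) and unstressed and stressed mice on the microglia-depleting PLX diet (Control-PLX and RSD-PLX). Each library pooled 3 mice, so a group is 2 pools and the spread is that between pools, not mice. For the gene tests it was estimated over all 4 groups of a class and drew on the other genes. For cell numbers it drew on the other classes, so those p-values do not measure the spread between the 2 pools of a group alone. Total counts per library ranged from 899206 UMI in RSD-PLX 1 to 9969844 UMI in RSD-Veh 2. The cohorts differed in depth, with median counts of 352 to 883.5 UMI per barcode in cohort 1 and 2360 to 2998 UMI in cohort 2. Barcodes with fewer than 200 genes made up 41.8% of Control-PLX 1 and 27.2% of RSD-PLX 1, against 2.46% of Control-Veh 1 and 5.10% of RSD-Veh 1, and 2.70% to 11.4% in cohort 2. After filters, 16944 cells fell into 17 classes named from marker genes, among them microglia-like, astrocyte-like, oligodendrocyte-like, endothelial-like, mural-like, choroid plexus-like, ependymal-like and neuron-like cells.

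The first question was whether the PLX diet depleted microglia, the resident macrophages of the brain. Microglia-like cells made up 39.1% ± 8.32 of cells in Control-Veh and 58.9% ± 5.92 in RSD-Veh, and 12.5% ± 2.67 in Control-PLX and 7.09% ± 0.83 in RSD-PLX (SD, n = 2 libraries each). Border macrophage-like cells, the macrophages of meninges and vessels, fell with PLX in control mice (log2 fold change −3.39 ± 0.79, adjusted p = 0.00132) and in stressed mice (adjusted p = 0.000145). In RSD-PLX, 0 of 1011 and 0 of 1079 cells outside the microglia-like class were of this class, which allows shares of up to 0.297% and 0.278%, while RSD-Veh had 13 and 24 such cells. Fibroblast-like cells, the collagen-making cells of meninges and vessels, fell with stress in vehicle mice (−2.02 ± 0.67, adjusted p = 0.0348) and rose with PLX in stressed mice (2.89 ± 0.68, adjusted p = 0.000475). Both calls use the RSD-Veh libraries, which held 12 and 7 such cells, so they are not separate evidence. PLX in control mice did not pass for this class (0.42, edgeR adjusted p = 0.642). Neuron-like cells, of which libraries held 14 to 108, fell with stress in vehicle mice (−2.18 ± 0.63, adjusted p = 0.0176) and with PLX in control mice (−2.14 ± 0.63, adjusted p = 0.0112). The interaction of stress and PLX passed for neuron-like cells as well (2.85 ± 0.89, adjusted p = 0.0383). Both falls and the interaction use the Control-Veh libraries, which held 108 and 100 such cells, so they are not separate evidence. The 6 calls that the 4 pairwise comparisons gave outside the microglia-like class became 2 without the replicate block, 3 with stricter cell filters, 3 without Control-Veh 2 and 11 with all cells as offset.

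Over both stress states the microglia-like share was 49.0% ± 12.9 on the control diet and 9.78% ± 3.5 on PLX (SD, n = 4 libraries each). The difference was −39.2 percentage points (two-sided exact permutation test, p = 0.0286, the smallest that 70 splits allow). Within cohorts the differences were −34.9 and −43.6 points, and an exact permutation test within cohorts gave p = 0.0556, the smallest that 36 splits allow. In edgeR the number of microglia-like cells fell with PLX in control mice (−1.65 ± 0.57, adjusted p = 0.0334) and in stressed mice (−3.04 ± 0.61, adjusted p = 0.000118). The difference between the PLX effects did not pass (adjusted p = 0.214), and neither did stress in vehicle mice (0.60, adjusted p = 0.406) nor stress in PLX mice (−0.79, adjusted p = 0.596). Dissociation, myelin removal, red cell lysis and the gene minimum, under which many cohort 1 PLX barcodes lay, can set all of these shares.

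**Figure D1:**
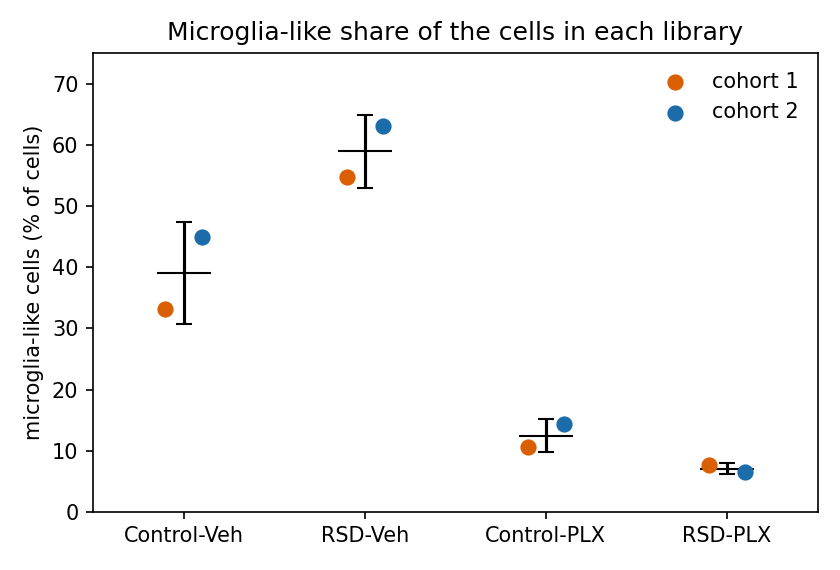
Microglia-like cells as a percent of all cells kept (vertical axis) in the 8 libraries, by group and cohort, with group means and SD (n = 2). The 4 PLX libraries lie between 6.50% and 14.4% and the 4 vehicle libraries between 33.2% and 63.1%.

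The next question was how the microglia-like cells of unstressed mice differed between the diets (Control-PLX against Control-Veh, n = 2 libraries each), whether by a change in surviving cells or a change in which cells were present. Microglia-like cells of Control-PLX carried more RNA of Lgals3, which encodes the lectin galectin-3 of activated macrophages (log2 fold change 4.75 ± 0.40, edgeR adjusted p = 2.41e-29). The gene, ENSMUSG00000050335, lies on the plus strand of GRCm38 chromosome 14 from 47367751 to 47386160. Ifi27l2a, an interferon-induced gene, was higher too (3.19 ± 0.31, adjusted p = 2.69e-21). Also higher were Lyz2, the macrophage lysozyme (2.29 ± 0.28), Apoe, the lipid carrier apolipoprotein E (2.14 ± 0.31), Cd74, the chaperone of MHC class II (2.02 ± 0.29), and Il1b, the cytokine interleukin 1 beta (2.31 ± 0.36). Lower were the purine receptors P2ry12 (−1.31 ± 0.28, adjusted p = 0.000645) and P2ry13 (−1.31 ± 0.28, adjusted p = 0.000527), and Tmem119, a surface protein of resting microglia (−1.27 ± 0.28, adjusted p = 0.00115). Csf1r, the receptor whose signal microglia need to survive, was at 0.06 ± 0.28 (adjusted p = 0.979) and Cx3cr1, the fractalkine receptor, at −0.37 ± 0.28 (adjusted p = 0.766).

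Among fixed lists in microglia-like cells, the disease-associated genes of activated microglia rose as a group, with 9 of 19 called and 13 adjusted over the list alone (camera adjusted p = 4.3e-12, and adjusted p = 0.58 with an estimated correlation). Lpl, a lipase (2.37 ± 0.36), and Cst7, a protease inhibitor (2.28 ± 0.38), were among them. NF-kB and cytokine genes rose too, with 9 of 17 called and 9 adjusted over the list alone (adjusted p = 1.6e-11, and adjusted p = 0.58 with an estimated correlation). They included Cd83 (1.80 ± 0.26), Gadd45b (2.39 ± 0.37) and Il1a (1.37). Interferon response genes rose, with 5 of 18 called and 8 adjusted over the list alone (adjusted p = 8.6e-07, and adjusted p = 0.58 with an estimated correlation). Ifitm3 was among them (2.07 ± 0.33). Immediate early genes rose, with 8 of 25 called and 13 adjusted over the list alone (adjusted p = 7.6e-17, and adjusted p = 0.58 with an estimated correlation). Ribosomal protein genes rose, with 5 of 43 called and 36 adjusted over the list alone (adjusted p = 7.3e-44, and adjusted p = 0.58 with an estimated correlation). Mitochondrially encoded genes lay above 0 as a group, with 0 of 13 called and 0 adjusted over the list alone (adjusted p = 0.00612, and adjusted p = 0.8 with an estimated correlation). Myelin genes, which mark another class, rose as a group, with 1 of 13 called and 2 adjusted over the list alone (adjusted p = 0.0173, and adjusted p = 0.723 with an estimated correlation). Homeostatic genes of resting microglia fell, with 5 of 17 called and 8 adjusted over the list alone (adjusted p = 4.8e-07, and adjusted p = 0.611 with an estimated correlation).

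Beyond microglia, Cd74 (1.65 ± 0.29, adjusted p = 0.0281) and the interferon-induced Ifit1 (2.16 ± 0.41, adjusted p = 0.0303) rose in fibroblast-like cells. Fos, an immediate early gene, rose in oligodendrocyte-like cells (1.30 ± 0.22, adjusted p = 0.0355). Clusters 15 and 6 held 283 and 222 of these cells in Control-Veh 1 and 17 and 316 in Control-PLX 1. In cohort 2 most lay in cluster 15 in both groups. Astrocyte-like cells held less RNA of the microglial genes C1qa (−2.44 ± 0.35), Tyrobp (−2.42 ± 0.40) and Ctss (−2.32). They held more Fos (2.18 ± 0.29) and Nr4a2 (2.23), both immediate early genes, together with more of the haemoglobin RNA Hba-a1 (2.22 ± 0.27). In all, 128 calls were higher and 55 lower over the classes tested, 99 and 31 of them in microglia-like cells, and 19 of the 183 were markers of another class. The cohorts moved the same way in 168 of the 183. In endothelial-like cells edgeR called 0 genes (196 at an unadjusted p under 0.05, DESeq2 0), and likewise 0 in mural-like cells (47, DESeq2 0) and in neuroblast-like cells (56, DESeq2 0). The microglia-like cells compared lay mostly in cluster 8 in Control-Veh 1, cluster 9 in Control-PLX 1, cluster 19 in Control-Veh 2 and clusters 3 and 22 in Control-PLX 2. Median counts were 850 UMI in cluster 8 and 461 UMI in cluster 9, and 883.5 and 352 UMI over all barcodes of Control-Veh 1 and Control-PLX 1. Without integration, cluster positions here and in the comparisons below cannot tell cell state from depth. Clusters 2 and 22 were led by Atf3, Ccl4, Ccl3, Fos and Cd83. Without Control-PLX 2 the 183 calls became 21. Without Control-Veh 1, RSD-Veh 1 or Control-PLX 1 they became 101 to 114, with stricter cell filters 108, and without the replicate block 23. Without Control-PLX 2 the values were 2.87 for Lgals3, 2.91 for Ifi27l2a and 0.45 for Fos in astrocyte-like cells, none of them called. The other called genes named here kept their direction but lost their call without at least 1 of Control-Veh 1, RSD-Veh 1, Control-PLX 1, Control-Veh 2 and Control-PLX 2, for example Lyz2 (1.62 to 2.63), Cd74 (0.76 to 2.26) and P2ry12 (−1.61 to −1.09) in microglia-like and C1qa (−8.55 to −2.09) in astrocyte-like cells.

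In stressed mice the same question was asked of RSD-PLX against RSD-Veh (n = 2 libraries each), which share no library with the comparison above. Microglia-like cells carried more Apoe (3.71 ± 0.33, edgeR adjusted p = 1.45e-26) and more Wfdc17, a secreted inhibitor-like gene of activated macrophages (3.38 ± 0.30, adjusted p = 6.54e-26). They also carried more Spp1, which encodes osteopontin (4.41 ± 0.41, adjusted p = 8.08e-24), and more Il1b (3.15 ± 0.30, adjusted p = 3.48e-23). Ccl12, a monocyte-attracting chemokine (2.79 ± 0.27), Tspo, the translocator protein used as a marker of activated microglia (2.08 ± 0.26), Fcgr4, an antibody receptor (2.87 ± 0.37), and Lgals3 (3.67 ± 0.57) were also higher. P2ry12 (−1.43 ± 0.29, adjusted p = 0.000287), Tmem119 (−1.56 ± 0.29, adjusted p = 3.49e-05), P2ry13 (−1.72 ± 0.35) and Tgfbr1, a receptor of the cytokine that maintains microglia (−1.34 ± 0.30), were lower. Csf1r was at −0.10 (adjusted p = 0.944) and Cx3cr1 at −0.60 (adjusted p = 0.381), and the median over all genes tested in this class was −0.17.

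Of the fixed lists, disease-associated genes rose in microglia-like cells, with 6 of 19 called and 10 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.5e-10, and adjusted p = 0.503 with an estimated correlation). Homeostatic genes fell, with 7 of 17 called and 10 adjusted over the list alone (adjusted p = 4.7e-09, and adjusted p = 0.505 with an estimated correlation). Ribosomal protein genes rose, with 10 of 43 called and 39 adjusted over the list alone (adjusted p = 3.8e-45, and adjusted p = 0.503 with an estimated correlation). Mitochondrially encoded genes rose, with 1 of 13 called and 1 adjusted over the list alone (adjusted p = 1.8e-05, and adjusted p = 0.577 with an estimated correlation). Nuclear genes of oxidative phosphorylation lay above 0, with 0 of 35 called and 0 adjusted over the list alone (adjusted p = 1.9e-11, and adjusted p = 0.56 with an estimated correlation). Of 99 genes that rose with PLX in control mice and 79 that rose in stressed mice, 40 were shared (1.06 expected of independent lists). Of 31 and 46 that fell, 15 were shared (0.194 expected). Both comparisons come from 1 fit with a shared estimate of the spread. Their lists are therefore not independent, and the expected numbers are only a reference.

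Endothelial-like cells of RSD-PLX carried more Ackr1, a chemokine-binding receptor of venules (1.95 ± 0.26, edgeR adjusted p = 0.00214), and more Lcn2, the iron-chelator-binding acute-phase protein lipocalin 2 (2.48 ± 0.40, adjusted p = 0.00989). Also higher were Fth1, the ferritin heavy chain (1.45 ± 0.24), and Insig1, a sterol-regulated gene (2.28 ± 0.42, adjusted p = 0.0146). Choroid plexus-like cells carried more RNA of the prolactin receptor Prlr (2.75 ± 0.58, adjusted p = 0.000775) and of Enpp2, which encodes the secreted enzyme autotaxin (2.25 ± 0.47, adjusted p = 0.000775). Mitochondrially encoded genes rose there too, with 4 of 12 called and 9 adjusted over the list alone (camera adjusted p = 3.5e-13, and adjusted p = 0.503 with an estimated correlation). These choroid results use the same 2 RSD-Veh libraries (30 and 55 such cells) as the comparison of stress in vehicle mice. Microglial genes fell in other classes, such as C1qa in astrocyte-like cells (−6.33 ± 0.47), C1qc in choroid plexus-like cells (at least 37-fold lower) and Tyrobp in endothelial-like cells (−3.93 ± 0.52). Over all classes 131 calls were higher and 143 lower, 79 and 46 of them in microglia-like cells, and 50 of the 274 were markers of another class. The cohorts moved the same way in 261 of the 274. EdgeR called 0 genes in mural-like cells (57 at an unadjusted p under 0.05, DESeq2 0). The 274 calls became 42 without RSD-Veh 2, 91 without RSD-PLX 2, 176 with stricter cell filters and 72 without the replicate block. Apoe, Wfdc17, Ccl12, Ifi27l2a, Fcgr4 and Cst7 in microglia-like cells were called whichever library was left out. The microglia-like cells lay mostly in clusters 9 and 2 in both cohort 1 libraries, clusters 19 and 22 in RSD-Veh 2 and clusters 3 and 22 in RSD-PLX 2. Cluster 27 of the endothelial-like cells, led by Ackr1 and Lrg1, held 62 and 27 cells in RSD-PLX 1 and RSD-PLX 2 against 41 and 2 in RSD-Veh 1 and RSD-Veh 2. Spp1 was not called without RSD-PLX 1 (1.82), Lgals3 not without RSD-Veh 2 (3.43), and Il1b and Tspo not without RSD-PLX 2 (1.93 and 1.19). In endothelial-like cells Ackr1, Lcn2, Fth1 and Insig1 were not called without RSD-Veh 2 (1.37, 1.51, 0.96 and 2.08), Insig1 also not without RSD-Veh 1 or RSD-PLX 1. Prlr and Enpp2 lost their call without RSD-Veh 1, RSD-PLX 1 or RSD-Veh 2 (1.83 to 4.26 and 1.44 to 2.98 over all libraries left out). P2ry12 (−1.87 to −1.20), Tmem119 (−2.51 to −1.18), P2ry13 and Tgfbr1 lost theirs without RSD-Veh 1 or RSD-Veh 2, among others.

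**Figure D2:**
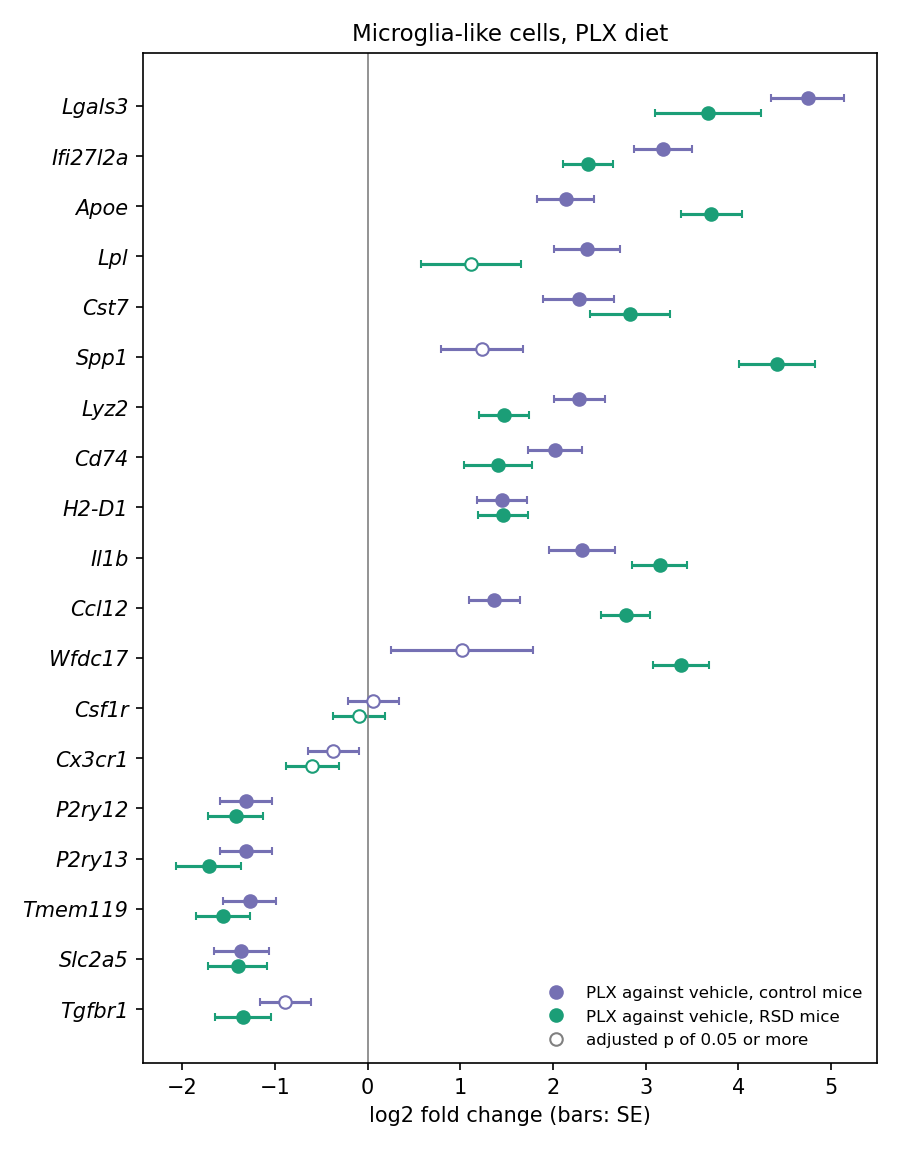
Log2 fold change with PLX (horizontal axis, with SE) of named genes in microglia-like cells of control and stressed mice, 2 libraries per group; open circles have an adjusted p of 0.05 or more. Apoe lies at 2.14 in control and 3.71 in stressed mice, P2ry12 at −1.31 and −1.43, and Csf1r near 0 in both.

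Next, stressed were compared with unstressed mice on the control diet (RSD-Veh against Control-Veh, n = 2 libraries each). Endothelial-like cells of stressed mice carried more Ackr1 (log2 fold change 6.17 ± 0.44, edgeR adjusted p = 4.43e-07), whose gene (ENSMUSG00000037872) lies on the minus strand of chromosome 1 from 173331886 to 173333750. More RNA was also found of Ifitm1, an interferon-induced membrane protein (3.77 ± 0.42, adjusted p = 0.000196), Lrg1, a secreted glycoprotein of inflamed vessels (4.60 ± 0.58, adjusted p = 0.000569), and Lcn2 (2.66 ± 0.48, adjusted p = 0.0219). In microglia-like cells Ifi27l2a (2.02 ± 0.27, adjusted p = 2.25e-10), Wfdc17 (2.39 ± 0.36, adjusted p = 4.48e-08) and Ifitm3 (1.05 ± 0.26, adjusted p = 0.0308) rose. The chemokine genes Ccl9 (−1.15 ± 0.23, adjusted p = 0.000721) and Ccl6 (−0.97 ± 0.23, adjusted p = 0.0113) fell. Choroid plexus-like cells, the epithelium that makes cerebrospinal fluid, carried less RNA of 107 genes. DESeq2 gave 50 calls in this class where edgeR gave 112. TMM factors there were 1.27 and 1.14 in RSD-Veh against 0.724 and 0.852 in Control-Veh, which moves all genes of this comparison downward. Prlr (−3.18 ± 0.55, adjusted p = 9.27e-06), 1500015O10Rik (−2.81 ± 0.48, adjusted p = 9.27e-06) and Enpp2 (−2.72 ± 0.47, adjusted p = 1.07e-05) fell. So did the mitochondrially encoded mt-Co1, a subunit of cytochrome c oxidase (−2.64 ± 0.47, adjusted p = 1.66e-05). In microglia-like cells P2ry12 was at −0.50 ± 0.27, Csf1r at 0.11 ± 0.26 and Cx3cr1 at −0.01 ± 0.27, none of which passed.

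By list, mitochondrially encoded genes fell in choroid plexus-like cells, with 10 of 12 called and 11 adjusted over the list alone (camera adjusted p = 4.7e-30, and adjusted p = 0.656 with an estimated correlation). Among them were mt-Nd1 (−2.53 ± 0.46) and mt-Co2 (−2.35 ± 0.46). In endothelial-like cells NF-kB and cytokine genes rose as a group, with 1 of 11 called and 3 adjusted over the list alone (adjusted p = 1.1e-05, and adjusted p = 0.656 with an estimated correlation). Mitochondrially encoded genes fell there as a group, with 0 of 13 called and 3 adjusted over the list alone (adjusted p = 2.4e-05, and adjusted p = 0.791 with an estimated correlation). Homeostatic microglia genes, which mark another class, lay above 0, with 0 of 11 called and 1 adjusted over the list alone (adjusted p = 0.00101, and adjusted p = 0.743 with an estimated correlation). Genes of angiogenesis and hypoxia rose with 0 of 11 called and 5 adjusted over the list alone (adjusted p = 5.8e-05, and adjusted p = 0.656 with an estimated correlation). In microglia-like cells immediate early genes rose as a group with 0 of 25 called and 7 adjusted over the list alone (adjusted p = 1.5e-28, and adjusted p = 0.656 with an estimated correlation). Ribosomal protein genes lay above 0 as a group there, with 0 of 43 called and 0 adjusted over the list alone (adjusted p = 2.7e-25), as did myelin genes, with 0 of 13 and 5 (adjusted p = 0.000287), and each had adjusted p = 0.656 with an estimated correlation. Interferon response genes rose there with 2 of 18 called and 2 adjusted over the list alone (adjusted p = 2.4e-05, and adjusted p = 0.656 with an estimated correlation). Homeostatic genes fell with 0 of 17 called and 1 adjusted over the list alone (adjusted p = 2.7e-05, and adjusted p = 0.656 with an estimated correlation). Markers of other classes moved as well. Ttr, the transthyretin RNA that fills choroid cells, fell in microglia-like (−3.13 ± 0.27) and endothelial-like cells (−6.05), and the microglial C1qb rose in choroid plexus-like cells (1.99, adjusted p = 0.00737), a call lost without Control-Veh 1, RSD-Veh 1, Control-Veh 2 or RSD-Veh 2 (1.71 to 2.22).

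The test gave 32 calls up and 120 down over all classes, and 140 of the 152 moved the same way in both cohorts. Of the calls up and down, 5 and 107 were in choroid plexus-like, 11 and 1 in endothelial-like and 7 and 5 in microglia-like cells, and 21 of the 152 were markers of another class. EdgeR called 0 genes in mural-like (58 at an unadjusted p under 0.05), neuroblast-like (55), erythrocyte-like (69) and oligodendrocyte precursor-like cells (22), and DESeq2 called 0 in each. The microglia-like cells lay mostly in cluster 8 in Control-Veh 1, clusters 9 and 2 in RSD-Veh 1, cluster 19 in Control-Veh 2 and clusters 19 and 22 in RSD-Veh 2. Most endothelial-like cells lay in clusters 10 and 4, and cluster 27, led by Ackr1, Lrg1, Vwf, Lcn2 and Ptgs2, held 41 and 2 of them in RSD-Veh 1 and RSD-Veh 2 against 3 and 0 in Control-Veh 1 and Control-Veh 2. The 152 calls became 66 with DESeq2, 54 with stricter cell filters, 29 without the replicate block, 71 to 91 without Control-Veh 2, RSD-Veh 2 or RSD-Veh 1 and 235 without RSD-PLX 2. Ackr1 and Ifitm1 were called whichever library was left out, and Lrg1 was not without Control-Veh 2 (3.59). Lcn2 was not called without Control-Veh 1, RSD-Veh 1 or Control-Veh 2 (lowest value 1.31), and the choroid genes named were not without RSD-Veh 1 or RSD-Veh 2, each of which had few such cells (30 and 55). In microglia-like cells Ifi27l2a was not called without Control-Veh 2 (2.04), Wfdc17 not without Control-Veh 2 or RSD-Veh 1 (1.97 and 2.18), and Ifitm3 (0.47 to 1.58), Ccl9 (−1.31 to −1.02) and Ccl6 (−1.32 to −0.60) not when any 1 library other than RSD-PLX 1 or RSD-PLX 2 was left out.

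**Figure D3:**
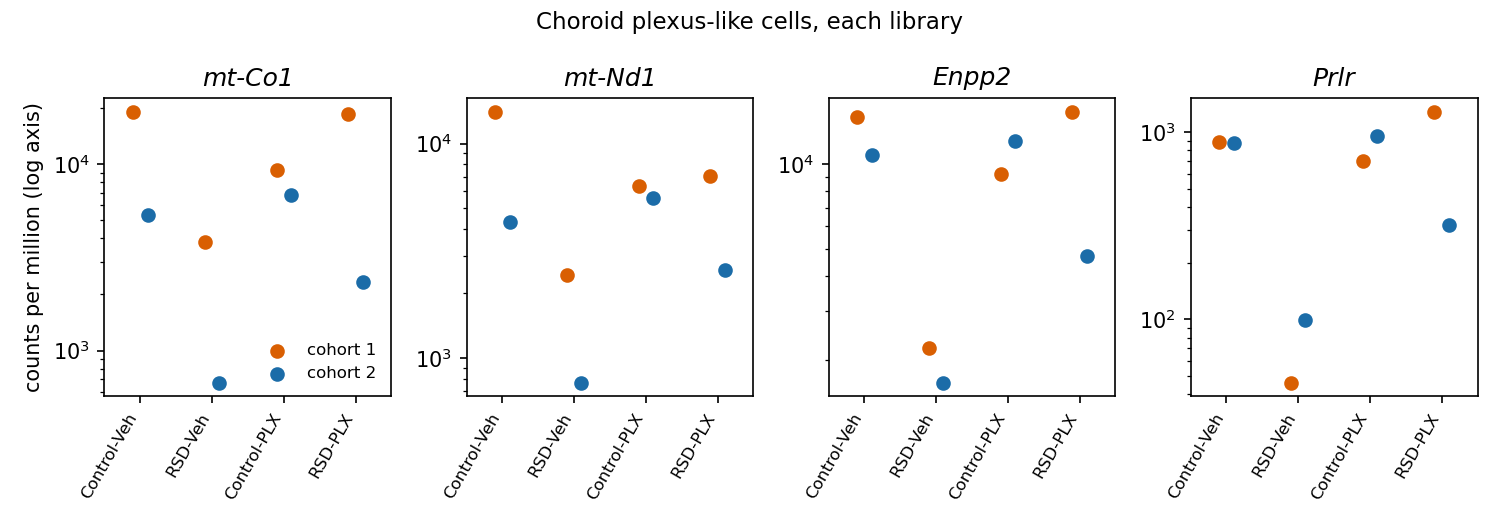
Level in choroid plexus-like cells of named genes in CPM (vertical axis, log scale) per library, by group and cohort. Enpp2 lies at 2200 and 1660 in RSD-Veh, and between 4710 and 15400 in the other libraries.

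In mice on the PLX diet, stress was tested as RSD-PLX against Control-PLX (n = 2 libraries each), libraries that the vehicle comparison does not share. Endothelial-like cells again carried more Ackr1 (log2 fold change 7.14 ± 0.43, edgeR adjusted p = 3.27e-08), Ifitm1 (5.06 ± 0.44, adjusted p = 4.62e-06), Lcn2 (5.85 ± 0.56, adjusted p = 8.87e-06) and Lrg1 (5.96 ± 0.66, adjusted p = 6.38e-05). They also carried more Fth1 (2.74 ± 0.25, adjusted p = 6.64e-06) and Ptgs2, the inducible cyclooxygenase (4.14 ± 0.71, adjusted p = 0.00386). Higher as well were Il1r1, the interleukin 1 receptor (2.98 ± 0.54, adjusted p = 0.00579), and Serpina3n, an acute-phase protease inhibitor that was at least 28.6-fold higher (adjusted p = 0.0101). In astrocyte-like cells Sult1a1, a sulfotransferase, rose (3.12 ± 0.38, adjusted p = 4.41e-13) and Nr4a1, an immediate early gene, fell (−3.54 ± 0.49, adjusted p = 5.82e-10). Microglia-like cells carried more Wfdc17 (4.75 ± 0.49, adjusted p = 1.01e-18) and Apoe (1.97 ± 0.31, adjusted p = 2.89e-07), and Csf1r (−0.05), Cx3cr1 (−0.24) and P2ry12 (−0.61) did not pass. Oligodendrocyte-like cells carried more Cdkn1a, a cell cycle inhibitor (4.76 ± 0.57, adjusted p = 0.000316), and Fkbp5, a glucocorticoid-induced co-chaperone of the glucocorticoid receptor (3.25 ± 0.62, adjusted p = 0.0306).

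By list, NF-kB and cytokine genes rose in endothelial-like cells with 4 of 11 called and 5 adjusted over the list alone (camera adjusted p = 1.3e-08, and adjusted p = 0.693 with an estimated correlation). Ribosomal protein genes rose there with 2 of 43 called and 4 adjusted over the list alone (adjusted p = 1.3e-09, and adjusted p = 0.693 with an estimated correlation). Immediate early genes, which dissociation can raise, fell as a group (adjusted p = 0.00051, and adjusted p = 0.693 with an estimated correlation). Of these 22 genes, 1 was called higher and 1 lower, and 2 were higher and 6 lower adjusted over the list alone. Angiogenesis and hypoxia genes rose with 2 of 11 called and 5 adjusted over the list alone (adjusted p = 0.0019, and adjusted p = 0.693 with an estimated correlation). The called members were Adm, a vessel-widening peptide (2.62 ± 0.42), and Hif1a, a transcription factor of low oxygen (1.97 ± 0.33). Glucocorticoid response genes rose with 1 of 14 called and 3 adjusted over the list alone (adjusted p = 0.0094, and adjusted p = 0.693 with an estimated correlation). Interferon response genes fell as a group (adjusted p = 0.0099, and adjusted p = 0.693 with an estimated correlation), although the 1 member of 22 that was called, also when adjusted over the list alone, was Ifitm3, which rose (1.07). Myelin genes fell with 2 of 8 called and 5 adjusted over the list alone (adjusted p = 4.8e-05, and adjusted p = 0.693 with an estimated correlation), Mbp at −1.97 among them. In oligodendrocyte-like cells glucocorticoid response genes rose with 2 of 13 called and 9 adjusted over the list alone (adjusted p = 1.1e-06, and adjusted p = 0.693 with an estimated correlation). In the same cells mitochondrially encoded genes lay above 0, with 0 of 13 called and 0 adjusted over the list alone (adjusted p = 2.6e-05), and immediate early genes below 0, with 1 of 19 and 2 (adjusted p = 0.00059), each at adjusted p = 0.693 with an estimated correlation. All 11 genes that rose in endothelial-like cells of vehicle mice were among the 73 that rose in PLX mice (0.147 expected of independent lists). Of the genes that rose in microglia-like cells, 4 of the 7 in vehicle mice were among the 12 in PLX mice (0.0114 expected). Here too 1 fit per class gave both lists with a shared estimate of the spread, so they are not independent and the expected numbers are only a reference.

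Over all classes 121 calls were higher and 78 lower, 73 and 25 of them in endothelial-like and 14 and 30 in astrocyte-like cells. All 98 endothelial-like calls moved the same way in both cohorts, but only 28 of the 44 astrocyte-like calls did. Of the calls, 23 of the 199 were markers of another class, such as Hba-a1 in astrocyte-like cells (−2.97). EdgeR called 0 genes in mural-like (87 at an unadjusted p under 0.05, DESeq2 0) and neuroblast-like cells (58, DESeq2 0). The microglia-like cells lay mostly in clusters 9 and 2 in cohort 1 and clusters 3 and 22 in cohort 2. The endothelial-like cells lay in clusters 10, 4 and 27, and cluster 27, which held 62 and 27 of them in RSD-PLX 1 and RSD-PLX 2 against 3 and 0 in Control-PLX 1 and Control-PLX 2, was led by Ackr1, Lrg1, Vwf, Lcn2 and Ptgs2. The 199 calls became 73 with DESeq2, 335 with no filter on low counts, 27 without the replicate block, 34 without Control-PLX 2, 73 without RSD-PLX 2 and 464 without RSD-PLX 1. Ackr1, Ifitm1, Lcn2, Lrg1 and Fth1 were called whichever library was left out, and Ptgs2, Il1r1 and Adm were not without Control-PLX 2 (3.48, 2.24 and 2.38). Hif1a and, in microglia-like cells, Apoe (1.56 to 2.47) were not called without Control-PLX 1 or Control-PLX 2. Sult1a1, Nr4a1, Cdkn1a, Fkbp5 and Serpina3n were not called without Control-PLX 2 or RSD-PLX 2. Without RSD-PLX 2, Nr4a1 was at 0.10, Sult1a1 at 1.42, Cdkn1a at 1.81 and Fkbp5 at 0.68.

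**Figure D4:**
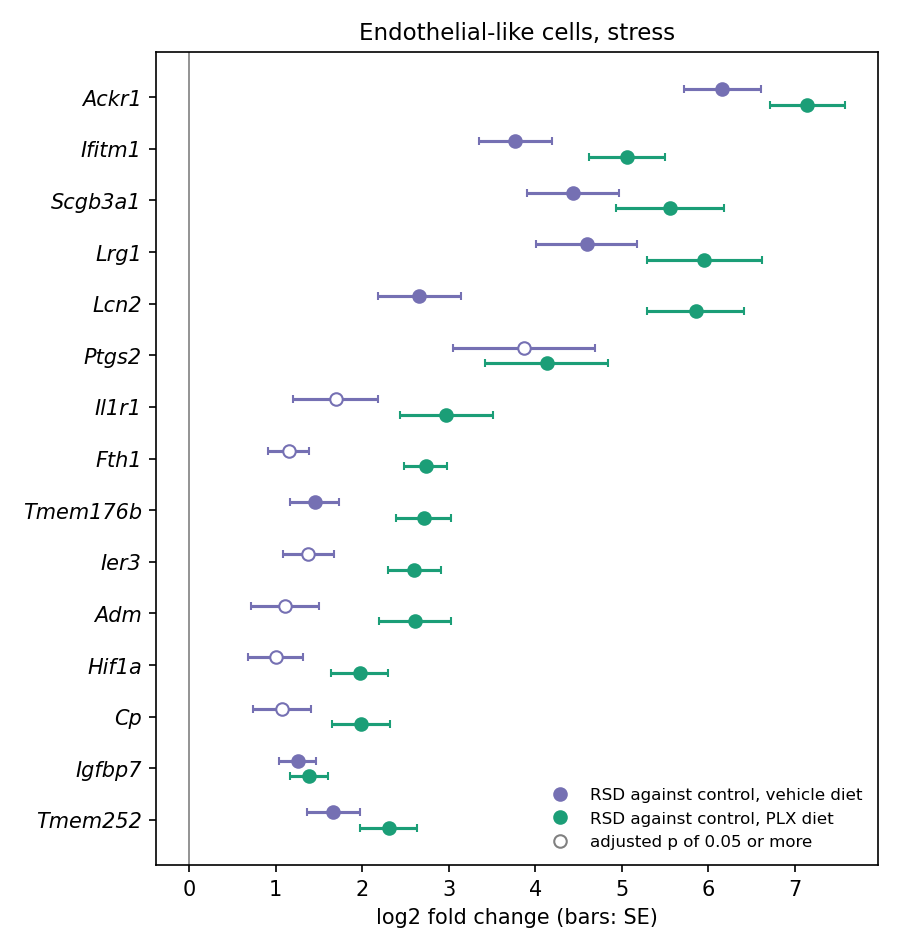
Log2 fold change with stress (horizontal axis, with SE) of named genes in endothelial-like cells of vehicle and PLX mice, 2 libraries per group; open circles have an adjusted p of 0.05 or more. Ackr1 lies at 6.17 and 7.14, and Ptgs2, Il1r1, Fth1, Ier3, Adm, Hif1a and Cp passed in PLX mice and not in vehicle mice. EdgeR called 0 genes in this class for the interaction, so these genes are not shown to differ between the diets.

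The last comparison asked where the response to stress differed between the diets, as the interaction of stress and PLX. Microglia-like cells gained more Spp1 with stress on PLX than on the control diet (log2 difference 3.18 ± 0.57, edgeR adjusted p = 0.000151). Endothelial Ackr1 (0.98 ± 1.06, adjusted p = 0.999), Lcn2 (3.20 ± 0.81, adjusted p = 0.93) and Ptgs2 (0.26 ± 2.03, adjusted p = 1) did not pass. As a group, endothelial NF-kB and cytokine genes lay above 0, with 0 of 11 called and 1 adjusted over the list alone (camera adjusted p = 0.00165, and adjusted p = 0.844 with an estimated correlation). Ribosomal protein genes did too, with 0 of 43 called and 0 adjusted over the list alone (adjusted p = 6.9e-10, and adjusted p = 0.844 with an estimated correlation). Choroid Enpp2 (2.43 ± 0.65, adjusted p = 0.0897) and mt-Co1 (2.24 ± 0.64, adjusted p = 0.108) did not pass either. The mitochondrially encoded genes passed as a group in choroid plexus-like cells, with 0 of 12 called and 9 adjusted over the list alone (camera adjusted p = 2.1e-10, and adjusted p = 0.844 with an estimated correlation). In astrocyte-like cells the interaction was negative for Junb (−3.12 ± 0.57, adjusted p = 3.72e-05) and Fos (−2.16 ± 0.52, adjusted p = 0.0207), both immediate early genes. The list of immediate early genes was lower than the other genes tested in microglia-like cells (0 of 25 called, 4 adjusted over the list alone, camera adjusted p = 1.9e-12). It was also lower in oligodendrocyte-like (0 of 19 and 5, adjusted p = 2.6e-09), endothelial-like (0 of 22, 5 lower and 1 higher, adjusted p = 9.6e-07) and mural-like cells (0 of 20 and 0, adjusted p = 0.00165). The list did not pass in astrocyte-like (adjusted p = 0.357), neuroblast-like (adjusted p = 0.302), neuron-like (adjusted p = 0.703) or choroid plexus-like cells (adjusted p = 0.815). With an estimated correlation the 4 that passed each had adjusted p = 0.844, and dissociation can raise these genes too. P2ry12 (−0.11), Csf1r (−0.16) and Cx3cr1 (−0.23) in microglia-like cells did not pass.

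The interaction was above 0 for 6 calls and below 0 for 16, and 15 of the 22 were markers of another class. Both cohorts moved the same way in 15 of the 22, in 7 of 12 in astrocyte-like and 1 of 3 in microglia-like cells. EdgeR called 0 genes in endothelial-like (254 at an unadjusted p under 0.05, DESeq2 0), choroid plexus-like (132, DESeq2 1), oligodendrocyte-like (164, DESeq2 0), neuroblast-like (61, DESeq2 0) and mural-like cells (38, DESeq2 0). The 22 calls became 1 with DESeq2, 0 without the replicate block, 7 without markers of other classes, 4 with stricter cell filters and 58 with no filter on low counts. They became 11 and 14 without RSD-Veh 2 and Control-PLX 2, and 55 to 66 without RSD-PLX 2, RSD-Veh 1, RSD-PLX 1 or Control-Veh 1. Spp1 was not called without RSD-PLX 1 (0.76), Control-Veh 2 (0.76) or RSD-Veh 2 (3.26). In astrocyte-like cells Junb was not called without RSD-Veh 1 (−2.48) or RSD-PLX 2 (−0.25) and turned without Control-PLX 2 (0.28). Fos there was called only when Control-PLX 1 or RSD-PLX 1 was left out, and was at −0.32 without Control-PLX 2 and −0.73 without RSD-PLX 2.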

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

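The tests of free RNA and of doublets given here were chosen after the result was seen. The free RNA test, first on the class medians alone, was then set against the pool of all cells, and the doublet test, first 1 test over both cohorts, was divided by cohort after its result. In this part, results stand out because the test of the difference between the stress effects on the 2 diets passed. In microglia-like cells Spp1 rose with stress on PLX by 3.18 (log2) more than on the control diet, a value that was 0.76 without RSD-PLX 1 or Control-Veh 2 and 5.65 and 5.42 without Control-PLX 2 and RSD-PLX 2. Spp1 stood at 874 CPM in RSD-PLX 1 against 16.8 CPM in Control-PLX 1, and at 33.4 CPM and 46.7 CPM in RSD-PLX 2 and Control-PLX 2. In astrocyte-like cells the interaction was −3.12 for Junb and −2.16 for Fos, both highest in Control-PLX 2, without which they were at 0.28 and −0.32. The haemoglobin genes Hba-a1, Hba-a2 and Hbb-bs had interactions of −3.01, −2.97 and −2.68 in astrocyte-like cells. None of the 3 was called without RSD-Veh 2 (−2.02, −0.57 and −0.62) or RSD-PLX 2 (−1.80, −0.99 and −1.13), Hba-a2 and Hbb-bs not without Control-Veh 2 (−2.06 and −1.99) and Hba-a2 not without Control-PLX 2 (−1.92). Ttr had 2.65 in the same cells, and the microglial genes C1qb and C1qa had −3.81 and −3.89. Ttr was at 4.50 without RSD-Veh 2, 3.98 without Control-PLX 2 and 4.34 without RSD-PLX 2. C1qb and C1qa were not called without Control-Veh 2 (−2.77 and −2.71), RSD-Veh 2 (−3.01 and −2.88) or RSD-PLX 2 (−8.08 and −7.48) and turned without Control-PLX 2 (2.99 and 2.25). In neuron-like cells the myelin gene Mbp had 5.03, a call lost without Control-Veh 2 (4.60), RSD-Veh 2 (4.37) or Control-PLX 2 (3.43), and the number of neuron-like cells itself had an interaction of 2.85.

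The pattern weighed is the lower level of microglial transcripts in other classes of PLX-fed stressed mice, 7 of which had at least 3 of the fixed markers tested (3 each in mural-like and neuron-like cells, and no gene was called in the former by edgeR, with 57 at an unadjusted p under 0.05 and 0 by DESeq2). Free RNA from microglia in the droplets, which would fall in every class as it falls in the pool of all cells, cannot be told apart from other causes. With groups at 0 set to a bound, the median of the fixed microglia markers in astrocyte-like cells was −5.29, or 1.66 below that of the pool (gap −1.66, log2). The gap was smaller in endothelial-like (−0.42), mural-like (−0.28), neuroblast-like (0.09) and neuron-like cells (−0.50), whose markers fell much as the pool did. In choroid plexus-like and oligodendrocyte-like cells the bound (−3.53 and −3.94) lay near the pool (−3.55 and −3.62) but the fitted medians lay lower (−5.80 and −4.97), so the size of the fall there is not known. Uncalled doublets of a microglia and another cell remain open in the shallow cohort, where 5% of the astrocyte-like cells of RSD-Veh 1 held 62.2% of the marker counts (95% interval 51.9 to 71.8%), against 31.5% when the counts were spread by depth. The deep cohort argues against doublets as the whole cause, since the same share was 23.6% in RSD-Veh 2 (20.7 to 26.7%), where 90.7% of the astrocyte-like cells held a marker count. That share was still above the 15.3% found when the counts were spread by depth, so a part played by doublets is not excluded there. A biological change within these other cells, in the stressed PLX-fed group, was not tested and stays open.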

How the results depend on the processing

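All alternatives here were chosen before the data were examined; in those that leave out a library, the lone library of its group is assumed to vary like the others, and where a result changed the cause was not tested. Calls for stress in vehicle mice (152) became 66 with DESeq2, 29 without the replicate block, 54 with stricter cell filters and 71 to 235 with 1 library left out; stress in PLX mice (199): 73 with DESeq2, 335 with no filter on low counts, 27 without the block, 34 to 464. PLX in control mice (183) became 23 without the block, 108 with stricter filters and 21 to 256 with 1 library left out, PLX in stressed mice (274) 72, 176 and 42 to 391. The interaction (22) gave 7 without markers of other classes, 1 with DESeq2, 58 with no filter, 0 without the block, 4 with stricter filters and 11 to 66 with 1 library left out. List calls (40, 36, 42, 44 and 22) became 0 in each comparison with an estimated correlation, and with 1 library left out 19 to 46, 16 to 44, 32 to 49, 30 to 56 and 10 to 41 (lowest without Control-Veh 2 and RSD-PLX 2 for stress, RSD-PLX 2 for the interaction). The microglia-like share difference of −39.2 points kept its direction (−44.5 to −34.5 with 1 library left out), and the exact permutation test within cohorts gave p = 0.0556. The 6 class abundance calls of the pairwise comparisons became 3 with stricter filters, 2 without the block, 11 with all cells as offset and 3 to 6 with 1 library left out. Of the log2 values of named genes, 262 were the same with doublets kept, 135 of 250 with DESeq2, 79 without the block and 170 of 231 with stricter filters. Keeping doublets returned at most the 1.28% of cells that were called and left the doublet clusters unnamed, so that setting could change little. Directions turned only in the values given next. Reversed values were 0.20 for Hba-a2 in microglia-like cells with stress in PLX mice (doublets kept), 0.04 and −0.04 for Csf1r with stress in PLX mice and PLX in control mice, and 0.02 for the interaction of P2ry12 (stricter filters). With 1 library left out, 21 of 2106 calls of named genes turned. Far more kept their direction but lost their call, so the few that turned do not show that the calls held. For stress in vehicle mice ranges were −6.43 to 0.22 for Hbb-bs, −9.92 to 0.35 for Hba-a1 and −5.60 to 0.46 for Hba-a2 in choroid plexus-like, and −0.96 to 2.82 for Ccl5, −0.18 to 0.36 for Csf1r and −0.19 to 0.16 for Cx3cr1 in microglia-like cells. For stress in PLX mice they were −3.35 to 0.62 for Junb, −4.31 to 0.10 for Nr4a1 and −0.09 to 2.56 for Bc1 in astrocyte-like, and −2.57 to 0.94 for Ttr, −0.33 to 4.59 for Spp1, −2.01 to 0.28 for Lgals3 and −0.52 to 0.24 for Csf1r in microglia-like cells. For PLX in control mice they were −1.20 to 3.4 for Junb and −0.55 to 1.90 for Btg2 in astrocyte-like, and −6.66 to 4.02 for Ccl5, −0.16 to 2.28 for Hbb-bt and −0.18 to 0.18 for Csf1r in microglia-like cells. For PLX in stressed mice they were −0.02 to 1.92 for mt-Nd3, −6.91 to 3.30 for Usp18 and −0.61 to 0.19 for Csf1r in microglia-like, and −0.86 to 2.57 for Cdkn1a in oligodendrocyte-like cells. For the interaction they were −8.08 to 2.99 for C1qb, −7.48 to 2.25 for C1qa and −4.45 to 0.28 for Junb in astrocyte-like, and −0.64 to 0.13 for Csf1r and −0.52 to 0.11 for P2ry12 in microglia-like cells. Microglia-like cells of PLX libraries were few in both cohorts, and over both cohorts 4.5% of simulated 2-fold changes were recovered in them with PLX in control mice.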

Other observations

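Of the tests in this part, those of Enpp2 against cytosol droplets and of venous genes were written before the result was seen, and those of nuclear RNA, of mixed microglia, of a few abundant genes and of neutrophil RNA were chosen after. The test of abundant genes first left out Ttr, whose share fell in RSD-Veh so that its removal was unable to end the pattern, and was replaced. The first planned neutrophil test, on the folds of S100a8 and S100a9, could not be run because neither passed the filter on low counts.

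Genes of cholesterol synthesis rose as a group in endothelial-like cells with PLX, in control mice (0 of 11 called, 4 adjusted over the list alone; camera adjusted p = 5.1e-09, and adjusted p = 0.58 with an estimated correlation) and in stressed mice (1 of 11 called, 6 adjusted over the list alone; adjusted p = 1e-07, and adjusted p = 0.503 with an estimated correlation). Insig1, the sterol-regulated brake on this pathway, was at 2.26 ± 0.47 in control mice, where it did not pass (edgeR adjusted p = 0.551). In endothelial-like cells of control mice immediate early genes rose too, with 0 of 22 called (camera adjusted p = 1.8e-06, and adjusted p = 0.611 with an estimated correlation). Homeostatic microglia genes fell, with 0 of 11 called and 7 adjusted over the list alone (adjusted p = 1.1e-09, and adjusted p = 0.58 with an estimated correlation). Clusters 10 and 4 held 186 and 185 endothelial-like cells in Control-Veh 1 and 260 and 54 in Control-PLX 1. In astrocyte-like cells the cholesterol synthesis list fell with stress in PLX mice, with 0 of 23 called and 12 adjusted over the list alone (adjusted p = 0.0022, and adjusted p = 0.693 with an estimated correlation). Mitochondrially encoded genes rose in these cells, with 0 of 13 called and 1 adjusted over the list alone (adjusted p = 0.0135, and adjusted p = 0.695 with an estimated correlation). Ribosomal protein genes lay above 0, with 0 of 43 called (adjusted p = 0.00051, and adjusted p = 0.693 with an estimated correlation). Glucocorticoid response genes rose in oligodendrocyte-like cells of stressed vehicle mice (0 of 13 called, 4 higher and 1 lower adjusted over the list alone; adjusted p = 7.3e-05, and adjusted p = 0.656 with an estimated correlation), as they did in PLX mice, where 9 were higher adjusted over the list alone. In vehicle mice these cells lay in clusters 15 and 6 in Control-Veh 1, cluster 6 in RSD-Veh 1 and cluster 15 in cohort 2. Mitochondrially encoded genes fell in ependymal-like cells, which line the ventricles, with stress in vehicle mice (1 of 11 called, 7 adjusted over the list alone, mt-Co1 at −0.70 ± 0.15 and not called without Control-Veh 1, Control-Veh 2 or RSD-Veh 2, at −0.77, −0.62 and −0.58; adjusted p = 1.4e-10, and adjusted p = 0.656 with an estimated correlation), and also with PLX in control mice (1 of 11 called, 7 adjusted over the list alone; adjusted p = 7.2e-14, and adjusted p = 0.58 with an estimated correlation). Both comparisons use Control-Veh 2, which had 11 such cells, and myelin genes rose in these cells with stress (2 of 9 called, 7 adjusted over the list alone; adjusted p = 2.7e-05, and adjusted p = 0.796 with an estimated correlation).

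In fibroblast-like cells interferon response genes rose with PLX in control mice (1 of 13 called, 5 adjusted over the list alone; adjusted p = 5.4e-07, and adjusted p = 0.611 with an estimated correlation) and fell with stress in PLX mice (1 of 13 called, Ifit1 at −3.37 ± 0.48 and not called without RSD-PLX 1 at −2.08, and 5 adjusted over the list alone; adjusted p = 1.1e-06, and adjusted p = 0.693 with an estimated correlation). The Control-PLX libraries stand on opposite sides of these comparisons, so spread in them alone gives opposite signs. Timp1, an inhibitor of matrix proteases, rose with stress in PLX mice (2.92 ± 0.38, edgeR adjusted p = 0.000198), a call lost without Control-PLX 2 (3.73) or RSD-PLX 2 (1.83). Cell cycle genes rose as a group in neuroblast-like cells with stress in PLX mice (0 of 15 called, 2 adjusted over the list alone; adjusted p = 0.00073, and adjusted p = 0.693 with an estimated correlation). Blood-brain barrier genes lay slightly above 0 as a group in endothelial-like cells with PLX in control mice, with 0 of 22 called and 0 adjusted over the list alone. Their median was 0.12 (camera adjusted p = 0.0073, and adjusted p = 0.58 with an estimated correlation). Immediate early genes rose by more in these cells (median 0.33, adjusted p = 1.8e-06, and adjusted p = 0.611 with an estimated correlation). Mitochondrially encoded genes lay below 0, with 0 of 13 called (adjusted p = 0.0354, and adjusted p = 0.8 with an estimated correlation).

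The 1st pattern weighed here is the lower RNA of mitochondrially encoded genes and of Enpp2 in choroid plexus-like cells in stressed vehicle mice. Among cells with a mitochondrial share at or above the 10th percentile of Control-Veh, the log2 difference of Enpp2 was still −1.97 and −1.60 in cohorts 1 and 2 (−2.01 and −2.32 over all cells). That cut lay at 0.641% and 0.115%, against 6.87% and 3.01% of all Control-Veh counts, so cells poor in mitochondrial RNA could pass it. The kept cells of RSD-Veh 1 held 41 Enpp2 counts. For Enpp2, droplets of cytosol without mitochondria are thus not excluded. For the mitochondrially encoded genes such droplets, without nucleus or mitochondria, cannot be told apart from other causes, since the nuclear RNA Malat1 changed by 0.22 in cohort 1 but −1.57 in cohort 2. There, cells at or above that share made up 50.9% in RSD-Veh 2 against 89.9% in Control-Veh 2 (21 of 30 cells against 128 of 143 in cohort 1). Mixed-in microglia are argued against by marker levels of at most 9.01% of those in microglia-like cells in RSD-Veh 1 (3.71% in RSD-Veh 2). A few abundant genes are argued against, since without the 10 genes that gained most in share in RSD-Veh the mitochondrial share still changed by −1.24 and −1.95 (log2, upper counting bounds −1.12 and −1.87), and those genes held 7.3% and 6.32% of counts. Damage to choroid cells in dissociation, the small cell numbers (30 and 55) and a response to stress itself were not tested and stay open.

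The 2nd pattern is the rise of Ackr1, Lrg1, Lcn2 and related genes in endothelial-like cells of stressed mice. RNA from neutrophils, which carry Lcn2, is argued against: at the neutrophil ratio of Lcn2 to S100a8, the S100a8 counts of endothelial-like cells of RSD-PLX 2 would bring 0.118% of their Lcn2 counts (upper bound 0.18%). A larger share of venous cells among those captured cannot be told apart from induction in the same cells, since the 3 tested venous genes had a median of 0.72 with values of 1.53 ± 0.45 for Nr2f2, 0.72 ± 0.27 for Slc38a5 and 0.26 ± 0.46 for Ephb4 in PLX mice, which lies between the bounds set for either. A response of venous endothelium to stress stays open as a hypothesis that these libraries did not test.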
